A study of Sus scrofa with 40 samples.

How the data were processed

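Messenger RNA was measured by RNA sequencing in 4 meat cuts of Chalu black pigs, with 10 libraries per cut: longissimus dorsi (LDM), hamstring (HM), trapezius (TM) and pork belly (PB). Per the labels' protocols the pigs were male offspring of one sire raised together, the tissue came from the left side of the carcass and was freed of fascia, RNA was extracted with Trizol and the libraries were made with a KAPA stranded kit. The submitters' processing notes name cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and the pig genome build Sscrofa11.1, without the role or the settings of each. The strand setting of the counting is not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical paralogs may therefore be split or shared between genes, and values of such genes are uncertain.

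The deposited table holds 21280 Ensembl genes with a whole-number read count and an FPKM value for each of the 40 libraries, per the file headers. The FPKM values of the authors equal the count scaled by the gene length given in the table and by the library total for 100% of the counts above 0, within a relative tolerance of 0.001, so they add nothing to the counts and were not tested. There were 0 lines that name no gene and 0 columns of values without a sample. Total counts per library ran from 12305913 to 17735722. Counting intervals are at 95% (exact, for a ratio of counts), and a count of 0 was set to a floor of 3 counts over the cut. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

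Gene symbols are those of the deposited table for 14883 IDs. A further 1282 were taken from reference tables of the same build by identifier or by position, with at least 50% reciprocal overlap, where the sources named no more than 1 symbol, and 5114 IDs stayed without one, 71 of them because their reference symbol was already in use. The remaining 1, a gene model that holds at least 80% of each of MYH4, MYH1 and MYH2, is written MYH4-MYH1-MYH2. Coordinates are those of the deposited table. No genome sequence was used here, so a trend with GC content was not checked.

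Libraries were placed in cuts by their titles. The first PB library, PB1, is titled and described as PB while its tissue and source fields name the longissimus. It was kept in PB, to whose mean it lay nearest, and left out in an alternative. No libraries of a cut were counted as 1: the lowest chi-square per gene between libraries of the same cut was 29.8, over genes with at least 20 counts.

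Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter by cut, which left 11713 genes, and a robust quasi-likelihood fit of all 40 libraries with the cut as the only factor. The 6 pairs of cuts were tested as contrasts and any difference among the 4 cuts with an F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. A second count also asks for an absolute log2 change of 1. Log2 changes are given with the SE of the fit, and CPM values as mean ± SD over 10 libraries. Principal components used log2 CPM with a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 25 lists in 6 pairs, and beside it with an estimated correlation and with fry. A list with fewer than 3 tested members was described by its members. Members were also counted with adjustment over the list alone.

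The pairs, the tests, the gene lists, the rule for named genes and the first group of alternatives named below were set before the data were examined. The rule names, per pair, the 5 highest and 5 lowest genes by log2 change among those with a symbol, an adjusted p under 0.05 and at least 1 CPM in the higher cut, up to 4 members of each list by smallest adjusted p, and MYH7, MYH4, MYH1, MYH2, ADIPOQ, LEP, FASN, SCD, PPARGC1A, MSTN, COL1A1 and PTPRC whatever their result. After results were seen, the list part was narrowed to the first 2 passing members of each list, to shorten the text. The 5 most abundant genes are also named. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

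These alternatives were DESeq2 size factors (RLE) and upper-quartile scaling in the same fit, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of at least 1 CPM in 10 libraries, the library number as a block, a fit of the 20 libraries of a pair alone, PB1 left out, and each library left out in turn. After the data were seen, 4 more were added: the 4 libraries nearest to the mean of another cut left out (HM6, HM9, TM3 and TM7), those of number 8 left out, the mitochondrially encoded genes taken out before scaling, and the block with a gene length correction. Ranges over alternatives omit each library left out in turn. Across genes, log2 change and log2 length had Spearman correlations of 0.165 in PB-LDM, 0.104 in PB-HM, 0.142 in PB-TM, 0.052 in TM-LDM, 0.077 in HM-LDM and -0.065 in TM-HM.

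The labels do not say that a library number marks a pig. After subtracting the cut means, 52 of 60 correlations between libraries of the same number in different cuts were above 0.1, the lowest was -0.128 and the mean 0.228, against -0.0252 for different numbers. By mean correlation 28 of 40 libraries matched their own number best, and in 10000 shuffles of the numbers the p was 1e-04, the smallest they can give. With 6 components removed the mean was 0.0223, 16 of 60 lay above 0.1 and the p was 0.1. Besides, the 4 libraries of number 8 had almost no counts of 3 Y-linked genes, and ENSSSCG00000044574 on chromosome 7 was on in all 4 cuts of 5 numbers and nearly off in all 4 cuts of the others. From this the numbers were taken to mark the same animal, an inference from the data and not from the labels, made before the calls of the blocked fit were looked at.

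The procedure was tested on simulated counts with 11713 genes drawn from the means and library sizes of the data. For PB against LDM, 29.9% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 4 of 136 calls were false (2.9%). For TM against HM the shares were 26.9%, 70.1% and 98.5%, with 2 of 132 calls false (1.5%). Tables and plots were made with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.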

Results

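Chalu black pigs are a pork breed, and the series measured messenger RNA in 4 meat cuts of these animals by RNA sequencing: the longissimus dorsi of the back (LDM), the hamstring of the hind leg (HM), the trapezius of the neck and shoulder (TM) and the pork belly (PB). Each cut had 10 libraries, 40 in all, and the labels name no reference cut, so the question addressed in each of the 6 pairs of cuts is which genes differ between them. Total counts per library ran from 12305913 to 17735722. The mean total was 15375232.5 ± 1295501 (SD, n = 10) in LDM, 14973981 ± 1005089.6 in HM, 15248551 ± 1108807 in TM and 14285689.9 ± 1220175 in PB. A single count was worth 0.0752 CPM (counts scaled to the library total) in HM1, so a gene below about 1 CPM rests on few reads. The labels number libraries 1 to 10 per cut without saying that a number marks a pig. Each p-value of the fit rests on the spread within cuts of 40 libraries, perhaps in part technical.

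The 5 most abundant genes over all libraries were skeletal actin ACTA1, the mitochondrial cytochrome oxidase subunit COX1, filamin FLNC, muscle creatine kinase CKM and a single gene model that spans the fast myosin heavy chains MYH4, MYH1 and MYH2, written here as MYH4-MYH1-MYH2. ACTA1 took 6.45% of all counts, COX1 3.16%, FLNC 3.14%, CKM 3.04% and MYH4-MYH1-MYH2 2.42%. That model, ENSSSCG00000029441, covers chromosome 12 from 55190429 to 55278539 on the Sscrofa11.1 build, so reads of the 3 fast myosins are summed in it and their separate levels were not analysed here. Mitochondrially encoded genes took 4.97% ± 0.826 of the counts in LDM, 7.53% ± 1.80 in TM, 9.12% ± 1.53 in HM and 12.5% ± 1.96 in PB (SD, n = 10 each).

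**Figure D1:**
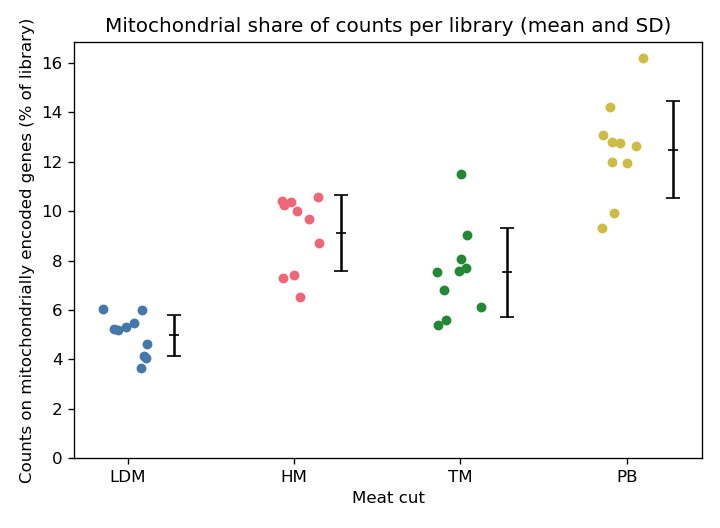
Share of each library's counts on mitochondrially encoded genes, in percent, for the 4 meat cuts. Each point is 1 library and the bar beside it is the mean with its SD (n = 10); the means run from 4.97% in LDM to 12.5% in PB.

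Over the 11713 genes with enough counts, 6695 differed among the 4 cuts (edgeR quasi-likelihood F test, adjusted p under 0.05), which is 57.2% of them. By correlation with the cut means over these genes, 10 of 10 LDM libraries, 8 of 10 HM, 8 of 10 TM and 10 of 10 PB lay nearest to their own cut. The 4 exceptions were HM6, which lay nearest to TM, HM9 and TM7, which lay nearest to LDM, and TM3, which lay nearest to HM. Over the 1000 most variable genes TM3 lay nearest to its own cut, and the other 3 as before.

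**Figure D2:**
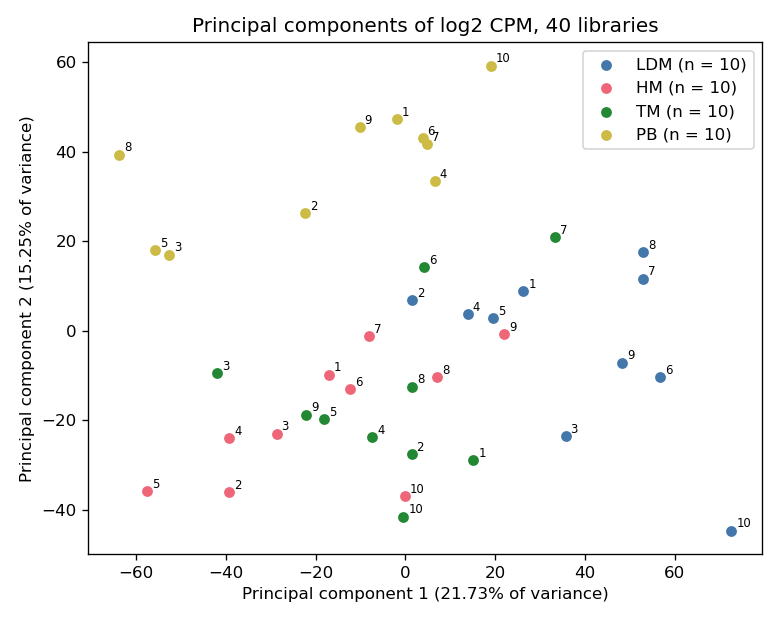
First 2 principal components of log2 CPM of the 11713 genes tested, with the share of variance on each axis. Each point is 1 of the 40 libraries, coloured by cut and marked with its number; the first component holds 21.7% of the variance and the second 15.2%.

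Belly and back were compared first. By camera the slow fibre list, proteins of slow, oxidative fibres, was higher in PB and the fast fibre and glycolysis lists lower (adjusted p = 1.29e-07, 8.39e-05 and 1.06e-07), with adjusted p = 0.47, 0.688 and 0.512 with an estimated correlation. All 13 slow fibre genes tested rose. The slow myosin heavy chain MYH7 (ENSSSCG00000002029, chromosome 7 from 75650445 to 75709232) stood at 26718 CPM ± 8589 in PB against 9078 ± 3462 in LDM (SD, n = 10 each), a log2 change of 1.56 ± 0.33 (SE, adjusted p = 0.000233), and was higher in 9 of 10 pairs of libraries with the same number. The Z-disc protein MYOZ2 was higher by 2.78 ± 0.40 and the slow tropomyosin TPM3 by 1.70 ± 0.27. Of 14 fast fibre genes 11 fell and 3 did not pass, among the former the calcium store protein CASQ1 at -1.04 ± 0.20 and TPM1 at -1.36 ± 0.26. Of 16 genes of glycogen breakdown and glycolysis, 15 fell, including glucose-6-phosphate isomerase GPI at -1.32 ± 0.23. GYS1, also in that list, makes glycogen instead and stood at -0.91 ± 0.14.

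Mitochondrially encoded genes rose in PB over LDM, 12 of 12 (adjusted p = 7.58e-20 by camera, adjusted p = 0.0201 with an estimated correlation). Among them were ND2 of complex I (ENSSSCG00000018069, mitochondrial chromosome from 5087 to 6128) at 6031 CPM ± 1633 against 793 ± 248 and a log2 change of 2.93 ± 0.20, and ATP6 of ATP synthase at 2.30 ± 0.16 (adjusted p = 7.52e-14 and 1.7e-13). ND2 was higher in 10 of 10 numbered pairs. Their median log2 change was 2.20. The nuclear-encoded oxidative phosphorylation genes had a median of 0.13, with 9 higher, 1 lower and 33 of 43 not passing; NDUFA4 was higher by 0.64 ± 0.11 and NDUFS1 by 0.57 ± 0.14. Of 24 genes of fatty acid uptake and oxidation 15 rose and 2 fell (adjusted p = 2.37e-05, adjusted p = 0.512 with an estimated correlation), led by DECR1 at 1.75 ± 0.18 and the medium-chain dehydrogenase ACADM at 1.66 ± 0.21. In the citric acid cycle 6 of 18 rose and 1 fell (adjusted p = 0.0469, adjusted p = 0.823 with an estimated correlation), with DLD at 1.11 ± 0.17 and PDHA1 at 0.75 ± 0.14.

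The highest log2 changes in PB over LDM were those of the kinase SBK2 (ENSSSCG00000033532, chromosome 6 from 59672295 to 59677670) at 7.07 ± 0.95, NPR3 at 5.36 ± 0.77, CLCA4 at 5.09 ± 0.68 and the plasminogen activator inhibitor SERPINB2 at 5.77 ± 1.27, with CPN2 at 2 counts over the 10 LDM libraries, a ratio of 99.6 in counts per total (95% counting interval 27.2 to 828). The ratio was 180.2 without LDM9 (31.9 to 7156) and 181 without LDM10 (32.0 to 7176). The lowest were HOXC10 at -4.49 ± 0.67, RASGEF1A at -3.27 ± 0.47, USH1C at -3.26 ± 0.65, IGFN1 at -3.21 ± 0.75 and GTSE1 at -2.92 ± 0.55. The transcription factor PRRX1 was higher by 2.01 ± 0.31, and of 23 positional factors 8 rose and 2 fell (adjusted p = 0.263 by camera). Of 19 lipid synthesis genes 3 rose and 4 fell (adjusted p = 0.847), with GPAM and MLXIPL higher by 1.86 ± 0.32 and 2.68 ± 0.47. Of 14 adipocyte genes 1 rose and 3 fell (adjusted p = 0.588), and among the latter CFD and GPD1 fell by 0.85 and 1.11. Of 49 cytosolic ribosomal protein genes 34 fell (adjusted p = 6.12e-10, adjusted p = 0.61 with an estimated correlation), with RPS16 at -0.98 ± 0.10 and RPL32 at -0.56 ± 0.09.

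The following lists did not pass by camera between PB and LDM. Of 26 matrix genes 11 rose (adjusted p = 0.0868), including the cross-linking enzyme LOX at 1.997 ± 0.504 and COL12A1 at 2.07 ± 0.53. Of 13 endothelial genes 3 rose (adjusted p = 0.167), with EMCN and ERG higher by 0.78 ± 0.16 and 0.86 ± 0.18, and of 10 smooth muscle and pericyte genes RGS5 alone passed, higher by 1.07 ± 0.19, while their median was -0.32 (adjusted p = 0.867). Of 8 Schwann cell genes 2 passed (adjusted p = 0.264): MBP and PRX fell by 1.35 and 1.21. At the neuromuscular junction 3 of 10 genes rose and 3 fell (adjusted p = 0.87), with UTRN and COLQ higher by 1.21 ± 0.21 and 1.60 ± 0.39. Of 16 heat shock genes HSPB6 and DNAJB4 passed, higher by 1.48 ± 0.31 and 1.21 ± 0.49 (adjusted p = 0.87). Of 21 immediate early genes 3 rose and 1 fell (adjusted p = 0.931), with SOCS3 and KLF6 higher by 2.83 ± 0.80 and 1.51 ± 0.44. Of 16 calpains, cathepsins and ubiquitin ligases 1 rose, the calpain inhibitor CAST by 0.71 ± 0.17, and 4 fell (adjusted p = 0.405), and the protease CAPN1 fell by 0.57. Of 12 myeloid genes ITGAM and CSF1R passed, higher by 0.90 ± 0.34 and 0.81 ± 0.33 (adjusted p = 0.847), and of 13 satellite cell and myogenic genes 2 passed, NCAM1 and MYMK, which fell by 0.96 and 1.19 (adjusted p = 0.435). In HOX groups 1 to 5, 1 of 11 genes passed and in groups 6 to 9, 2 of 9 (adjusted p = 0.847 and 0.104): HOXD1, HOXC9 and HOXC8 fell by 2.39, 1.59 and 1.30. In groups 10 to 13, 1 of 5 rose and 1 fell (adjusted p = 0.682). HOXA13 had 0 counts in LDM and 9 in PB, a ratio of 3.23 against a floor of 3 counts over the cut, and of 1.59 without PB10. At so few PB counts these are no lower bounds. Among the genes fixed beforehand, the leukocyte gene PTPRC was higher by 1.44 ± 0.45 (adjusted p = 0.00983).

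The fast myosin model MYH4-MYH1-MYH2 did not pass in PB against LDM, at -0.08 ± 0.23 (adjusted p = 0.819), nor did ADIPOQ at 0.13 ± 0.57, FASN at -0.30 ± 0.28, SCD at 0.00 ± 0.39, PPARGC1A at -0.08 ± 0.65, MSTN at 0.40 ± 0.38 and COL1A1 at 0.72 ± 0.39. In this pair 4880 genes passed, 2397 higher and 2483 lower in PB (49.1% higher), and 1417 by 2-fold or more, 1120 higher and 297 lower. The larger side turned with the scaling: 2735 were higher and 1952 lower (58.4% higher) with the mitochondrial genes taken out before scaling, 2559 and 2249 (53.2%) with DESeq2 size factors, and 2399 each with upper-quartile scaling, within a range of 46.8% to 58.4% over the alternatives. Without PB8, at 26.1 CPM of PTPRC against 1.55 to 5.16 in the rest of PB, PTPRC stood at 0.53 (adjusted p = 0.232) and the adjusted p of COL1A1 was 0.0474, without LDM3 that of NCAM1 was 0.0525, and without LDM2 that of MSTN was 0.0491. ITGAM lost its call without LDM10, PB2 or PB8 (adjusted p up to 0.3), CSF1R without LDM3, LDM4, LDM7, LDM8, LDM9, PB2, PB3, PB4 or PB8 (up to 0.179) and DNAJB4 without LDM3, LDM6, LDM7, LDM8, LDM9, LDM10, PB3, PB5 or PB8 (up to 0.158). HOXC8 lost its call without HM4, LDM1, LDM5, LDM7, LDM8, LDM9, PB2, PB3, PB5, PB9 or PB10 (adjusted p up to 0.0633), and MYMK without any 1 of 29 libraries, most of all LDM8 (adjusted p = 0.134). The log2 change of SERPINB2 was 4.03 without PB8 and 7.65 without LDM2, that of SOCS3 1.97 without PB8, and that of COL12A1 1.37 without PB1. Without PB10, which held 5 of the 9 HOXA13 counts of PB, IGFN1 stood at -3.99 and USH1C at -4.06. With the number as a block SERPINB2, SOCS3 and IGFN1 stood at 4.92, 1.96 and -3.896, and COL12A1 and ITGAM no longer passed (adjusted p = 0.0547 and 0.0951). With the block and a length correction these, PTPRC and MYMK did not pass (adjusted p = 0.117, 0.387, 0.0559 and 0.0887). FASN then did (0.0436), and COL12A1 and NPR3 stood at 1.145 and 4.68. With limma-voom SERPINB2 and SOCS3, then at 2.005 and 1.17, PTPRC, at 0.66, HOXA13, ITGAM, DNAJB4, NCAM1, CSF1R and MYMK no longer passed (adjusted p from 0.0583 for NCAM1 to 0.315 for ITGAM, and 0.198 for SOCS3). COL12A1, HOXD1, IGFN1, NPR3 and SBK2 then stood at 1.21, -2.99, -3.81, 4.52 and 5.85. Without the libraries of number 8 SOCS3, PTPRC, ITGAM, CSF1R, DNAJB4, NCAM1, MYMK and HOXC8 no longer passed (adjusted p from 0.0504 for SOCS3 to 0.345 for ITGAM). COL1A1 then did (0.0346), and SERPINB2 and SOCS3 stood at 3.903 and 1.91. CSF1R, DNAJB4, HOXC8 and MYMK also lost it with no filter, and DNAJB4 and ITGAM on the pair alone. MYMK lost it too with DESeq2 size factors, without PB1 and with the mitochondrial genes taken out. Over the alternatives the adjusted p ran from 6.53e-05 to 0.191 for SERPINB2, 0.000376 to 0.198 for SOCS3 and 0.0104 to 0.223 for HOXA13. It was 0.00258 to 0.302 for PTPRC, 0.0151 to 0.387 for ITGAM, 0.0253 to 0.188 for DNAJB4, 0.00704 to 0.0675 for NCAM1, 0.0253 to 0.234 for CSF1R and 0.0368 to 0.214 for MYMK. It was 0.00381 to 0.0703 for HOXC8, 0.000202 to 0.117 for COL12A1, 0.0436 to 0.541 for FASN and 0.0346 to 0.598 for COL1A1.

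Camera with a preset correlation called 7 of 25 lists between PB and LDM, of which mitochondrially encoded genes alone passed with an estimated correlation. Adjusted over the list alone, the same numbers held for slow fibre (13), fast fibre (11), glycolysis (15) and mitochondrial (12) genes, with 15 higher and 3 lower in fatty acid oxidation, 6 and 1 in the citric acid cycle and 35 lower ribosomal genes. Without PB1 the citric acid cycle no longer passed (adjusted p = 0.0549), nor with fry (0.0599).

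**Figure D3:**
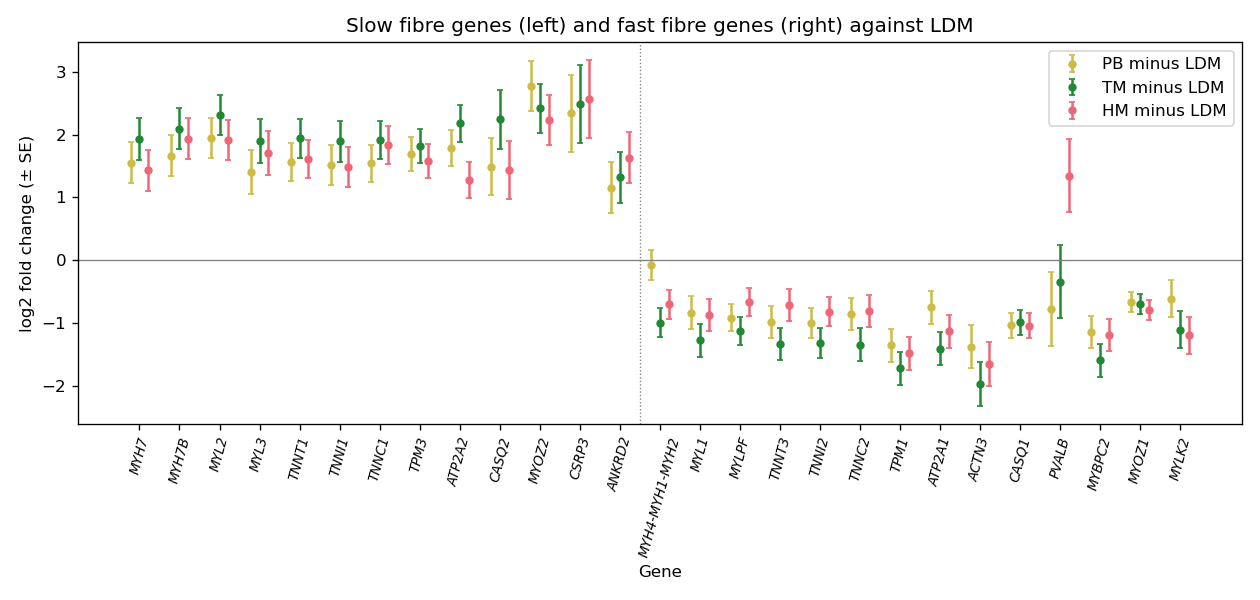
Log2 fold change with its SE of each tested slow fibre gene (left of the dotted line) and fast fibre gene (right) in PB, TM and HM against LDM, fitted over 40 libraries with n = 10 per cut. The 13 slow fibre genes lie above 0 in all 3 comparisons, with medians of 1.56 in PB, 1.94 in TM and 1.64 in HM.

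Trapezius and back were compared next, and the 3 comparisons against LDM share its libraries. By camera slow fibre and fatty acid oxidation genes were higher in TM and fast fibre and glycolysis genes lower (adjusted p = 2.13e-12, 1.49e-07, 1.48e-12 and 3.02e-18), with adjusted p = 0.255, 0.397, 0.269 and 0.177 with an estimated correlation. The slow myosin MYH7 stood at 34616 CPM ± 19565 in TM against 9078 ± 3462 in LDM, a log2 change of 1.93 ± 0.33 (adjusted p = 5.13e-05), and was higher in 9 of 10 numbered pairs. All 13 slow fibre genes rose, among them the calcium pump ATP2A2 at 2.18 ± 0.29 and the slow light chain MYL2 at 2.32 ± 0.32. Of 14 fast fibre genes 13 fell, including TPM1 at -1.72 ± 0.26 and MYBPC2 at -1.60 ± 0.26, and MYH4-MYH1-MYH2 fell by 0.99. All 16 glycolysis genes fell, with GPI at -1.69 ± 0.23 and PGK1 at -1.75 ± 0.26. Of 24 fatty acid genes 16 rose and 1 fell, led by CPT2 at 1.60 ± 0.25 and ACAA2 at 1.19 ± 0.19.

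The genes farthest apart between TM and LDM were SBK2 at 6.23 ± 0.92, RFLNA at 5.82 ± 0.72, METTL21C at 5.23 ± 0.94, DDN at 4.45 ± 0.97 and NRSN1 at 4.45 ± 0.80, and in the other direction HOXC10 (ENSSSCG00000022728, chromosome 5 from 19197807 to 19202970) at -6.27 ± 0.76, HOXA9 at -5.47 ± 1.36, SIM1 at -3.60 ± 0.70 and USH1C at -3.21 ± 0.63. HOXA10 had 1 count over the 10 TM libraries, which gives a ratio of LDM to TM of 289 (95% counting interval 51.4 to 11440). It was 181 without LDM3 (32.0 to 7181) and 151 without LDM4 (26.6 to 6009), and without TM7 the gene was at least 86.3-fold higher in LDM against the floor of 3 counts. By camera lipid synthesis, matrix, endothelial, mitochondrially encoded and oxidative phosphorylation genes were higher in TM and ribosomal protein genes lower (adjusted p = 0.0224, 5.82e-05, 2.56e-05, 5.35e-06, 0.000108 and 1.92e-07), with adjusted p = 0.467, 0.688, 0.476, 0.47, 0.823 and 0.688 with an estimated correlation. Of 19 lipid synthesis genes 5 rose and 1 fell, and MLXIPL and GPAM were higher by 2.998 ± 0.474 and 2.02 ± 0.33. Of 14 adipocyte genes 1 rose, the glycerol channel AQP7 by 2.30 ± 0.35, and 1 fell (adjusted p = 0.375 by camera), and GPD1 fell by 1.46. Of 26 matrix genes 6 rose, with SPARC at 0.65 ± 0.18 and THBS4 at 1.37 ± 0.39, and 10 of 13 endothelial genes rose, with FLT1 at 0.78 ± 0.17 and ERG at 0.81 ± 0.18. ND2 and ATP6 were higher by 0.86 ± 0.18 and 0.68 ± 0.16 among 11 of 12 mitochondrially encoded genes that rose. NDUFA4 and ATP5MC3 were higher by 0.59 and 0.56 among 11 of 43 nuclear-encoded oxidative phosphorylation genes that rose, and PDHA1 and IDH2 by 0.62 each among 4 of 18 citric acid cycle genes that rose, with 1 lower (adjusted p = 0.0583). RPS16 and RPL7 fell by 0.55 and 0.50 among 18 of 49 ribosomal protein genes that fell.

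Of 23 other positional factors 9 rose and 1 fell in TM against LDM (adjusted p = 0.0537 by camera), and of 11 HOX genes of groups 1 to 5, 5 rose and 1 fell (0.287). Of 9 in groups 6 to 9, 4 fell (0.000771, and adjusted p = 0.298 with an estimated correlation), and of 5 in groups 10 to 13, 3 fell (0.0819). IRX3 and MEOX1 were higher in TM by 3.36 ± 0.59 and 2.07 ± 0.35, HOXB2 and HOXC4 by 1.14 ± 0.24 and 1.79 ± 0.43, and HOXC9 fell by 2.22. Of 13 satellite cell and myogenic genes 1 rose and 3 fell. Among these myostatin, MSTN, which restrains muscle growth, fell by 2.12 and was lower in 8 of 10 numbered pairs, and the perinatal myosin MYH8 fell by 2.18. Of 10 neuromuscular junction genes 3 rose, with CHRNA1 and COLQ at 1.33 ± 0.35 and 1.34 ± 0.39, and RGS5 alone of 10 smooth muscle genes, CSF1R alone of 12 myeloid genes and TP63 alone of 4 skin genes passed, at 0.85 ± 0.19, 0.87 ± 0.33 and -1.22. Of 16 heat shock genes HSPB6 rose by 1.86 ± 0.31 and HSPB8 fell by 1.17, and of 8 Schwann cell genes PMP2 rose by 1.70 ± 0.57 and MBP fell by 1.39. Of 16 calpains, cathepsins and ubiquitin ligases 3 were lower, and CAPN1 and CAPN3 fell by 0.54 and 0.60. Of 21 immediate early genes KLF6 rose by 1.35 ± 0.44 and 2 were lower, and DUSP1 fell by 0.84. By camera the lists from satellite cells to immediate early genes did not pass, with adjusted p from 0.0562 for smooth muscle to 0.757 for skin genes. The values of ADIPOQ at 0.64 ± 0.57, FASN at -0.08 ± 0.28, SCD at 0.72 ± 0.38, PPARGC1A at 0.68 ± 0.65, COL1A1 at 0.60 ± 0.39 and PTPRC at 0.07 ± 0.45 did not pass.

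Between TM and LDM 2898 genes passed, 1325 higher and 1573 lower in TM (45.7% higher), and 720 by 2-fold or more, 442 higher and 278 lower. Upper-quartile scaling gave 1611 higher and 1219 lower (56.9% higher), and the pair alone 1623 and 1438 (53%). Without TM6 the adjusted p of PMP2 was 0.367 and its log2 change 0.61, against 2.33 without LDM1, and with the number as a block it stood at 1.05 (adjusted p = 0.119). PMP2 also lost its call with the block and a length correction, on the pair alone, with DESeq2, where it stood at 0.54, and with limma-voom, at 0.83 (adjusted p = 0.0185 to 0.381 over its alternatives). Without TM3 the adjusted p of KLF6 was 0.146. DUSP1 lost its call without LDM4, LDM6, TM5, TM7 or TM10 (adjusted p up to 0.0734) and CSF1R without any 1 of 18 libraries, most of all TM8 (adjusted p = 0.102). Without TM7, which held the 1 HOXA10 count of TM, HOXC10 stood at -7.84 and USH1C at -4.59. LDM3 and LDM4 held 127 and 156 of the 291 HOXA10 counts of LDM and most HOXA9 counts. HOXA9 stood at -4.76 without LDM3 and -4.82 without LDM4. Without TM10, METTL21C stood at 4.62, NRSN1 at 3.78 and DDN at 3.77, and DDN at 5.07 without LDM10. With limma-voom HOXA10, DDN and DUSP1 no longer passed (adjusted p = 0.152, 0.0551 and 0.0701, within ranges of 1.15e-05 to 0.152, 3.17e-06 to 0.0551 and 0.0137 to 0.0701). Values of DDN, HOXA9, HOXC9, HOXC10, METTL21C, NRSN1, RFLNA, SBK2, SIM1 and USH1C were then 3.53, -3.87, -3.34, -7.59, 3.33, 3.19, 4.99, 5.30, -4.28 and -4.74. Without HM6, HM9, TM3 and TM7, DUSP1 and KLF6 no longer passed (adjusted p = 0.0619 and 0.0773, for KLF6 within a range of 0.00748 to 0.0773). CSF1R did not with no filter or without number 8 (adjusted p = 0.0654 and 0.122, within a range of 0.0134 to 0.122). On the pair alone COL1A1 passed (adjusted p = 0.019, within a range of 0.019 to 0.312).

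Camera called 11 of 25 lists between TM and LDM and 0 with an estimated correlation, under which 5 had an unadjusted p under 0.05, while fry called 13 but not oxidative phosphorylation (adjusted p = 0.104). Adjusted over the list alone, the numbers of slow fibre (13), fast fibre (13), glycolysis (16) and ribosomal protein genes (18) held. By the same count 13 of 43 oxidative phosphorylation, 16 fatty acid, 7 lipid synthesis, 10 matrix, 11 endothelial and 12 mitochondrial genes and 1 HOX gene of groups 6 to 9 were higher, and 2 fatty acid, 2 lipid synthesis and 6 HOX genes of groups 6 to 9 lower. With the number as a block the other positional factors also passed (adjusted p = 0.0449, against 0.0537 without it).

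HOX genes of the posterior groups, which pattern the hind end of the body, were higher in HM than in LDM, 4 of 5 tested in groups 10 to 13 (adjusted p = 1.33e-11 by camera, adjusted p = 0.00182 with an estimated correlation). HOXA13 (ENSSSCG00000029666, chromosome 18 from 45373440 to 45380300) stood at 15.3 CPM ± 6.60 in HM and had 0 counts over the 10 LDM libraries, at least 791-fold higher in HM against a floor of 3 counts over the cut. HOXA11 and HOXC11 were higher by 7.02 ± 0.56 and 5.40 ± 0.56, and the myosin kinase MYLK4 by 5.72 ± 0.53, each in 10 of 10 numbered pairs. CPN2 had 2 counts in LDM, a ratio of 166 (95% counting interval 45.7 to 1379). HM3 held 198 of its 324 counts in HM, and without HM3 the ratio was 72.0 (19.52 to 601), against 301 without LDM9 (53.7 to 11930) and 302 without LDM10 (53.8 to 11960). Of 9 HOX genes in groups 6 to 9, 2 rose and 5 fell, of 11 in groups 1 to 5, 2 fell, and of 23 other positional factors 9 rose and 4 fell (adjusted p = 0.132, 0.475 and 0.513). HOXC8, HOXC5 and HOXC6 fell by 5.27, 4.22 and 3.86, and NRN1 and SIM1 stood at -5.33 and -4.01. HOXD1 fell by 2.54, and SHOX2 was higher by 1.97 ± 0.34.

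In HM against LDM, slow fibre, fatty acid oxidation, mitochondrially encoded and oxidative phosphorylation genes were higher by camera and fast fibre and glycolysis genes lower (adjusted p = 2.61e-08, 0.00306, 2.69e-12, 0.000965, 1.06e-07 and 6.63e-13), with adjusted p = 0.47, 0.712, 0.165, 0.823, 0.476 and 0.292 with an estimated correlation. MYH7 was higher by 1.43 ± 0.33, TNNC1 by 1.83 ± 0.30 and MYL2 by 1.91 ± 0.32, with 13 of 13 slow fibre genes higher. MYH4-MYH1-MYH2 fell by 0.70, TPM1 by 1.49 and CASQ1 by 1.05, with 13 of 14 fast fibre genes lower, and 15 of 16 glycolysis genes fell, including TPI1 at -1.44 ± 0.23 and GPI at -1.35 ± 0.23. DECR1 and CPT2 were higher by 1.02 ± 0.17 and 1.30 ± 0.24 among 13 of 24 fatty acid genes that rose, and 2 fell. ND2 and ND3 were higher by 1.45 ± 0.19 and 1.14 ± 0.16, with 12 of 12 mitochondrially encoded genes higher. NDUFA4 and COX5B were higher by 0.55 and 0.57 among 11 of 43 nuclear-encoded oxidative phosphorylation genes that rose, and PDHA1 and MDH2 by 0.76 and 0.49 among 6 of 18 citric acid cycle genes that rose, with 1 lower (adjusted p = 0.0869 by camera).

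The endothelial, smooth muscle and matrix lists passed by camera as higher in HM than in LDM (adjusted p = 3.97e-06, 0.00628 and 0.00291), and did not with an estimated correlation (adjusted p = 0.47, 0.688 and 0.823), nor did matrix with fry (adjusted p = 0.0747). CDH5 and ERG were higher by 1.07 ± 0.17 and 1.13 ± 0.18, with 10 of 13 endothelial genes higher, and RGS5 and MYLK by 1.14 ± 0.19 and 1.26 ± 0.31, with 9 of 10 smooth muscle genes higher. In MYLK, HM6 stood at 483 CPM against 28.5 to 73.0 in the rest of HM, and without HM6 the log2 change was 0.55. TNC and COL15A1 were higher by 3.08 ± 0.64 and 0.70 ± 0.19 among 12 of 26 matrix genes that rose. Of 19 lipid synthesis genes 6 rose and 1 fell, with GPAM and ACACA higher by 1.67 ± 0.32 and 0.99 ± 0.19, and of 14 adipocyte genes AQP7 rose by 1.496 ± 0.343 and 3 were lower, and GPD1 fell by 1.27. Of 10 neuromuscular junction genes 4 rose, with CHRNA1 and CHRNE at 1.68 and 1.26, and of 13 satellite cell and myogenic genes 2 rose and 2 fell, with IGF2 at 0.77 and CDH15 at -0.96. MBP alone of 8 Schwann cell genes and TP63 alone of 4 skin genes passed, at -1.45 and -1.68, and of 16 calpains, cathepsins and ubiquitin ligases 4 were lower, among them CAPN3 and NEDD4 at -0.70 and -1.58. HSPB6 and CRYAB of 16 heat shock genes were higher by 1.61 and 0.93. By camera the lists from lipid synthesis to heat shock genes did not pass, with adjusted p from 0.0823 for lipid synthesis to 0.899 for Schwann cell genes. Of 21 immediate early genes 5 rose (adjusted p = 0.0474, adjusted p = 0.823 with an estimated correlation), with CCN2 and EGR1 at 1.08 and 2.48. HM5 stood at 4903 CPM of EGR1 against 114 to 734 in the rest of HM, and without HM5 the log2 change was 0.97 (adjusted p = 0.175). Of 49 ribosomal protein genes 24 fell and 1 rose (adjusted p = 1.69e-09, adjusted p = 0.615 with an estimated correlation), with RPS16 and RPL10 at -0.71 and -0.61. ADIPOQ at -0.20 ± 0.57, FASN at -0.06 ± 0.28, SCD at 0.66 ± 0.38, PPARGC1A at 0.70 ± 0.65, MSTN at -0.65 ± 0.39, COL1A1 at 0.63 ± 0.39 and PTPRC at 0.56 ± 0.45 did not pass.

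Between HM and LDM 3805 genes passed, 1932 higher and 1873 lower in HM, and 956 by 2-fold or more, 629 higher and 327 lower. The share of higher genes was 50.8%, and 45% to 54.8% over the alternatives. CRYAB lost its call without HM2, HM5 or LDM7 (adjusted p up to 0.0712). Without HM6 the log2 change of SIM1 was -6.23 and that of HOXC5 -4.84. Without LDM4, HOXA11 stood at 8.26 and HOXC11 at 6.45, and without HM9 HOXD1 at -3.21. With limma-voom EGR1, HOXC11, HOXD1, MYLK4, NRN1 and SIM1 stood at 1.65, 6.49, -3.87, 4.68, -3.42 and -5.76, and with the number as a block EGR1 at 1.73. Camera called 12 of 25 lists, of which HOX groups 10 to 13, tilted towards HM by the filter, alone passed with an estimated correlation. Adjusted over the list alone, 4 HOX genes of groups 10 to 13, 13 slow fibre, 11 oxidative phosphorylation, 14 fatty acid, 14 matrix, 11 endothelial, 9 smooth muscle, 4 immediate early and 12 mitochondrial genes were higher. Lower by the same count were 13 fast fibre, 15 glycolysis and 25 ribosomal protein genes, with 1 fast fibre gene, PVALB, and 1 ribosomal protein gene higher and 2 fatty acid genes lower. The immediate early genes no longer passed without PB1 or without number 8 (adjusted p = 0.0524 and 0.0606). With fry these and the oxidative phosphorylation genes did not pass (adjusted p = 0.176 and 0.104).

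Between PB and HM, 4 of 5 tested HOX genes of groups 10 to 13 were lower in PB (adjusted p = 3.58e-13 by camera, adjusted p = 0.000869 with an estimated correlation). HOXA13, HOXA11, HOXC11, HOXC10 and MYLK4 were lower in PB, at -7.64, -6.83, -6.70, -5.42 and -4.45, while IRX3 (ENSSSCG00000002831, chromosome 6 from 31046098 to 31048822), SIM1, IRX5, HOXC5 and HOXC8 were higher by 5.89 ± 0.69, 5.56 ± 0.74, 4.64 ± 0.66, 4.21 ± 0.66 and 3.98 ± 0.60. ND5 and ND2 were higher in PB by 2.01 ± 0.24 and 1.48 ± 0.19, with 10 of 12 mitochondrially encoded genes higher (adjusted p = 3.19e-10, adjusted p = 0.199 with an estimated correlation). MYLK and the smooth muscle actin ACTA2 fell by 1.52 and 1.67, with 8 of 10 smooth muscle genes lower (adjusted p = 0.00337, adjusted p = 0.684 with an estimated correlation). HM6 stood at 3168 CPM of ACTA2 against 147 to 556 in the rest of HM, and without HM6 ACTA2 stood at -0.96 and MYLK at -0.76. CDH5 and PECAM1 fell by 0.88 and 0.84, with 5 of 13 endothelial genes lower (adjusted p = 0.00352, adjusted p = 0.688 with an estimated correlation). Of 13 slow fibre genes 0 passed in edgeR, 0 had an unadjusted p under 0.05 and 0 passed in DESeq2 or limma-voom, with MYH7 at 0.13 ± 0.32 (adjusted p = 0.81).

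Of 24 fatty acid genes 5 rose and 1 fell in PB against HM, with the fatty acid transporter CD36 and the electron carrier ETFA higher by 1.26 and 0.58, and of 18 citric acid cycle genes 3 rose and 1 fell, with DLD and SUCLA2 higher by 0.93 and 0.75. In the glycogen and glycolysis list 2 of 16 rose and 1, glycogen synthase GYS1, fell by 0.69. Of 19 lipid synthesis genes 5 were lower, with LPIN1 and ACSS2 at -0.90 and -0.65, of 14 adipocyte genes CFD alone passed, at -0.62, and of 43 oxidative phosphorylation genes COX5B of complex IV and NDUFB5 of complex I passed, at -0.42 and -0.39. Of 14 fast fibre genes 1 rose and 1, the calcium-binding protein PVALB, fell by 2.13. Of 26 matrix genes 2 rose and 3 fell, with the collagens COL4A2 and COL15A1 at -0.99 and -0.79. Of 10 neuromuscular junction genes 3 were lower, among them LRP4 and CHRNE at -0.78 and -1.02, and of 8 Schwann cell genes 2, SOX10 and GFAP at -1.49 and -1.20. Of 16 heat shock genes the chaperone CRYAB alone passed and fell by 1.149. Of 13 satellite cell and myogenic genes 2 rose and 4 fell, with the cadherin CDH15 at 0.67 and the growth factor IGF2 at -0.65, and of 16 calpains, cathepsins and ubiquitin ligases 4 rose and 2 fell, with the ubiquitin ligase NEDD4 and the calpain inhibitor CAST at 2.13 and 0.89. HOXC6 was higher by 2.91 among 2 of 9 HOX genes of groups 6 to 9 that rose, and HOXA4 by 0.80 in groups 1 to 5, where 2 of 11 rose and 1 fell. Of 23 other positional factors 5 rose and 5 fell, and of 49 ribosomal protein genes 5 rose, RPL7 and RPS6 by 0.55 and 0.36 among them, and 12 fell. By camera these lists did not pass, with adjusted p from 0.0515 for fatty acid genes to 0.909 for HOX groups 6 to 9. Of 21 immediate early genes CCN2 and FOSB passed, at -1.05 and -1.35 (adjusted p = 0.0474 by camera, adjusted p = 0.823 with an estimated correlation). Of the genes fixed beforehand, MYH4-MYH1-MYH2 and MSTN were higher by 0.62 ± 0.23 and 1.05 ± 0.39 (adjusted p = 0.0413 and 0.041), and ADIPOQ at 0.33 ± 0.57, FASN at -0.24 ± 0.28, SCD at -0.66 ± 0.39, PPARGC1A at -0.78 ± 0.65, COL1A1 at 0.09 ± 0.39 and PTPRC at 0.88 ± 0.44 did not pass.

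Between PB and HM 3232 genes passed, 1583 higher and 1649 lower in PB (49% higher), and 908 by 2-fold or more, 603 higher and 305 lower. With the mitochondrial genes taken out before scaling, 1936 were higher and 1139 lower (63% higher), within a range of 45.7% to 63%. Without HM9 PVALB stood at -1.152 (adjusted p = 0.1), and with the number as a block at -1.504. Without HM6 the adjusted p of SOX10 was 0.0556, without HM1 that of CHRNE was 0.0844 and without PB5 that of PPARGC1A was 0.0429. HOXA4 lost its call without HM5, PB6, PB7 or PB8 (adjusted p up to 0.0661), MYH4-MYH1-MYH2 without HM2, HM3, HM4, HM5, HM10, PB1, PB4, PB6 or PB10 (up to 0.117) and MSTN without HM2, HM3, HM4, HM6, HM8, HM10, PB1, PB6, PB7, PB8 or PB10 (up to 0.0985). NDUFB5, FOSB and GFAP lost theirs without any 1 of 24, 31 and 33 libraries, most of all LDM7, HM5 and HM6 (adjusted p = 0.127, 0.145 and 0.174). Without HM6, SIM1 stood at 7.83 and HOXC5 at 4.91. Without PB10, HOXA13 stood at -8.51 and HOXA11 at -9.73, and without PB7 HOXC11 at -7.29. Without number 8 COX5B, NDUFB5 and MSTN no longer passed (adjusted p = 0.0955, 0.144 and 0.0974). COX5B then stood at -0.26. With limma-voom PVALB, SOX10 and HOXA4 no longer passed (adjusted p = 0.117, 0.375 and 0.0626), with PVALB at -1.22 and SOX10 at -0.86, and MYLK4 and SIM1 stood at -3.63 and 7.38. Without HM6, HM9, TM3 and TM7, PVALB, then at -0.71, GFAP and HOXA4 no longer passed (adjusted p = 0.318, 0.105 and 0.0908). PVALB, at -1.41, and MYH4-MYH1-MYH2 did not with the block and a length correction (0.0689 and 0.14). FOSB, GFAP and NDUFB5 also lost their call with DESeq2 size factors, no filter, without PB1, with the mitochondrial genes taken out and on the pair alone, NDUFB5 with DESeq2 too. MSTN lost it with no filter and without PB1, and MYH4-MYH1-MYH2 with upper-quartile scaling, without PB1 and on the pair alone. Over the alternatives the adjusted p ran from 0.00225 to 0.0955 for COX5B, 0.00434 to 0.144 for NDUFB5, 0.0163 to 0.0974 for MSTN and 0.0022 to 0.318 for PVALB. It was 0.00725 to 0.375 for SOX10, 0.0109 to 0.0908 for HOXA4, 0.00893 to 0.105 for GFAP, 0.0021 to 0.0812 for FOSB and 0.00837 to 0.14 for MYH4-MYH1-MYH2.

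Camera called 5 of 25 lists between PB and HM, of which HOX groups 10 to 13, tilted towards HM by the filter, alone passed with an estimated correlation. Adjusted over the list alone, 4 HOX genes, 5 endothelial, 8 smooth muscle and 1 immediate early gene were lower and 10 mitochondrial genes higher. Without PB1 the immediate early genes no longer passed (adjusted p = 0.0664), nor with fry (0.178).

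In belly against trapezius, ND2 and ND5 were higher in PB by 2.06 ± 0.19 and 2.57 ± 0.25, ND2 in 10 of 10 numbered pairs, with 11 of 12 mitochondrially encoded genes higher (adjusted p = 8.35e-20 by camera, adjusted p = 0.0201 with an estimated correlation). Of 13 slow fibre genes 0 passed in edgeR, 0 had an unadjusted p under 0.05 and 0 passed in DESeq2 or limma-voom, with MYH7 at -0.37 ± 0.32 (adjusted p = 0.419). MYH4-MYH1-MYH2 was higher by 0.92 ± 0.23 and MSTN by 2.52 ± 0.42 (adjusted p = 3.14e-05). SIM1 (ENSSSCG00000004357, chromosome 1 from 67214337 to 67294397) and the kinase PRKG1 were higher by 5.15 ± 0.72 and 3.73 ± 0.73, HOXA9 by 7.31 ± 1.38 and SERPINB2 by 5.29 ± 1.21. HOXA10 had 1 count over the TM libraries, a ratio of 910 (95% counting interval 163.0 to 36000.0). HOXA13 had 0 in TM, for a ratio of 3.20 against the floor and 1.58 without PB10, which at so few PB counts are no lower bounds. PB9 and PB10 held 380 and 471 of the HOXA10 counts of PB and 2050 and 1017 of HOXA9, with 0 or 1 and 0 to 16 in the other 8. The HOXA10 ratio was 559 without PB9 (99.9 to 22130) and 453 without PB10 (80.8 to 17920), and without TM7 the gene was at least 272-fold higher in PB.

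CEACAM1, ADAMTS8, STAC2, ZIC1 and the myoblast fusion factor MYMK were the lowest in PB against TM and fell by 2.51, 2.42, 2.25, 2.22 and 2.14. Of 24 fatty acid genes 4 rose and 1 fell, with DECR1 and ACADM higher by 0.90 ± 0.17 and 0.90 ± 0.20, and of 18 citric acid cycle genes 3 rose, with DLD and SUCLA2 at 0.89 and 0.69. Of 43 oxidative phosphorylation genes 1 rose and 2 fell, with NDUFS4 of complex I at 0.46 and its partner NDUFB10 at -0.33. CFD alone of 14 adipocyte genes passed, at -0.53. Of 26 matrix genes 2 rose and 3 fell, with POSTN at 2.26 and COL4A2 at -0.78. Of 8 Schwann cell genes 4 were lower, among them PRX and SOX10 at -1.49 each, and of 10 neuromuscular junction genes 1, UTRN, rose by 0.84 and 2 were lower, with DOK7 at -0.60. Of 13 satellite cell and myogenic genes 3 rose and 2 fell, and of 23 other positional factors 3 rose and 7 fell. HOXA7 was higher by 1.90 in HOX groups 6 to 9, where 2 of 9 rose and 1 fell, HOXB3 and HOXB4 fell by 1.26 and 1.57 among 3 of 11 in groups 1 to 5 that fell, and 2 of 5 in groups 10 to 13 rose. Of 16 heat shock genes DNAJB4 and DNAJA1 passed, higher by 1.88 and 1.96, and of 16 calpains, cathepsins and ubiquitin ligases 3 rose and 1 fell, with CAST and NEDD4 at 0.91 and 1.83. By camera these lists did not pass, with adjusted p from 0.0776 for Schwann cell genes to 0.853 for satellite cell genes. By camera glycolysis genes were higher and lipid synthesis, smooth muscle and endothelial genes lower (adjusted p = 0.0217, 0.0474, 0.0469 and 0.0439), with adjusted p = 0.823, 0.513, 0.823 and 0.823 with an estimated correlation. Of 16 glycolysis genes 2 rose, PHKA1 of glycogen breakdown by 0.79, and 1 fell. The lipid genes FADS2 and SREBF1 fell by 0.98 and 0.65 as 2 of 19, NOTCH3 and TAGLN by 0.90 and 0.83 among 3 of 10 smooth muscle genes, and TIE1 and PECAM1 by 0.45 and 0.59 as 2 of 13 endothelial genes. Of 49 ribosomal protein genes 4 rose, RPL7 and RPS6 by 0.55 and 0.36 among them. The other 12 that passed fell (adjusted p = 0.00593, and adjusted p = 0.823 with an estimated correlation). PTPRC was higher by 1.36 ± 0.45, and ADIPOQ at -0.51 ± 0.57, FASN at -0.22 ± 0.28, SCD at -0.72 ± 0.39, PPARGC1A at -0.75 ± 0.65 and COL1A1 at 0.12 ± 0.39 did not pass.

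Between PB and TM 2706 genes passed, 1571 higher and 1135 lower in PB (58.1% higher), and 748 by 2-fold or more, 605 higher and 143 lower. Upper-quartile scaling gave 1427 higher and 1593 lower (47.3% higher), and taking out the mitochondrial genes 1802 higher and 726 lower (71.3% higher). Without number 8, 1482 were higher and 625 lower (70.3% higher). With the number as a block, ADAMTS8, DNAJA1 and PTPRC no longer passed (adjusted p = 0.0754, 0.065 and 0.0512, within ranges of 0.0114 to 0.0895, 0.00114 to 0.316 and 0.00753 to 0.232). With limma-voom HOXA10, HOXA9, HOXA13, SERPINB2, SOX10 and SREBF1 no longer passed (adjusted p = 0.134, 0.13, 0.224, 0.417, 0.0736 and 0.0533, within ranges of 7.07e-08 to 0.134, 7.61e-10 to 0.13, 0.0121 to 0.224, 0.000669 to 0.417, 0.00543 to 0.0736 and 0.0106 to 0.0827), nor did DNAJA1 and PTPRC (0.316 and 0.232). HOXA9, SERPINB2 and DNAJA1 stood at 3.05, 1.40 and 0.54. CEACAM1, DNAJB4, PRKG1 and SIM1 then stood at -3.27, 1.28, 1.93 and 5.91. With the number as a block HOXA9, PRKG1 and SERPINB2 stood at 5.56, 2.84 and 3.95. Without number 8 ADAMTS8, HOXA13, CFD, DNAJA1, DOK7, NDUFB10, PECAM1, PTPRC, SREBF1, TAGLN and TIE1 no longer passed (adjusted p from 0.05 to 0.165), and SERPINB2, DNAJA1 and PTPRC stood at 3.50, 1.19 and 0.66. CFD, NDUFB10 and PHKA1 lost their call with the block and a length correction, as did ADAMTS8, DNAJA1 and PTPRC, with ADAMTS8 at -1.52, DNAJA1 at 1.31 and POSTN at 1.64. PHKA1, PECAM1, TIE1 and PTPRC lost it on the pair alone. PECAM1, TIE1 and DOK7 lost it with no filter, without PB1 and with the mitochondrial genes taken out, and NDUFB10 with the last. PECAM1 and TIE1 lost it with DESeq2 size factors, ADAMTS8 and TAGLN with no filter, and DOK7 without HM6, HM9, TM3 and TM7. Over the alternatives the adjusted p ran from 0.00594 to 0.108 for CFD, 0.000887 to 0.0841 for DOK7, 0.00666 to 0.0959 for NDUFB10 and 0.0013 to 0.102 for PECAM1. It was 0.00338 to 0.0616 for PHKA1, 0.00591 to 0.0963 for TAGLN, 0.00358 to 0.164 for TIE1 and 0.0041 to 0.0849 for POSTN. Without PB8 PTPRC stood at 0.46 and DNAJA1 at 1.17 (adjusted p = 0.364 and 0.0719), SERPINB2 at 3.54 and PRKG1 at 3.09. Without PB10 the adjusted p of HOXA13 was 0.0716, without PB1 that of POSTN, then at 1.504, was 0.0849, and without TM10 that of SREBF1 was 0.0852. ADAMTS8 lost its call without TM4 or TM5 (adjusted p up to 0.0978), PHKA1 without PB10 or TM10 (up to 0.116), CFD without TM6, TM7 or TM8 (up to 0.129), NDUFB10 without HM9, LDM5, LDM7 or LDM9 (up to 0.0572) and TAGLN without PB8, PB9, TM1, TM3, TM5 or TM8 (up to 0.122). PECAM1, TIE1 and DOK7 lost theirs without any 1 of 18, 20 and 20 libraries, most of all TM3 for PECAM1 and TM6 for the others (adjusted p = 0.106, 0.0994 and 0.0867). HOXA9 stood at 5.96 without PB9 (PB10 kept), CEACAM1 at -3.12 without PB3 and SERPINB2 at 5.93 without TM3 and 6.08 without TM9.

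Camera called 7 of 25 lists between PB and TM, of which mitochondrially encoded genes alone passed with an estimated correlation. Fast fibre genes, 1 of 14 members, were also higher (adjusted p = 0.0224, adjusted p = 0.823 with an estimated correlation). Adjusted over the list alone, 11 mitochondrial, 1 fast fibre, 2 glycolysis and 4 ribosomal protein genes were higher and 1 glycolysis, 2 lipid synthesis, 5 endothelial, 4 smooth muscle and 13 ribosomal protein genes lower. Lipid synthesis, endothelial and smooth muscle genes no longer passed without PB1 (adjusted p = 0.0525, 0.058 and 0.0553), nor did the endothelial and smooth muscle genes without number 8 (adjusted p = 0.0526 and 0.084). With fry the fast fibre, glycolysis, endothelial, smooth muscle and ribosomal protein genes did not pass (adjusted p = 0.178, 0.196, 0.0991, 0.0817 and 0.155). With the number as a block the Schwann cell genes also passed as lower (adjusted p = 0.0488, against 0.0776 without it).

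Trapezius and hamstring gave the fewest called genes of the 6 pairs, 90, with 9 of 25 lists called by camera. Of 5 HOX genes in groups 10 to 13, 5 were lower in TM, in groups 1 to 5, 2 of 11 were higher and 1 lower, in groups 6 to 9, 2 of 9 higher and 2 lower, and of 23 other positional factors 2 higher and 1 lower (adjusted p = 1.11e-42, 0.000577, 0.271 and 0.143 by camera, adjusted p = 6.48e-09, 0.199, 0.823 and 0.688 with an estimated correlation). HOXA13 had 0 counts in TM and 2310 in HM, at least 784-fold lower in TM against a floor of 3 counts over the cut. HOXA10, HOXA11 and HOXC11 had 1, 2 and 3 counts in TM, for ratios of HM to TM of 2930 (95% counting interval 525 to 115800.0), 547 (151 to 4525) and 409 (139.7 to 1988). Without TM7 HOXA10 was at least 876-fold and without TM6 HOXA11 at least 331-fold lower in TM against the floor, and without TM6 the HOXC11 ratio was 1115 (199.8 to 44090). HOXA9 fell by 8.11 in TM, and IRX3, HOXC5, IRX5 and ZNF385A (ENSSSCG00000000292, chromosome 5 from 19560317 to 19583221) were higher by 6.52 ± 0.71, 5.04 ± 0.66, 4.47 ± 0.66 and 3.47 ± 0.43. HOXC6 was higher by 3.38 ± 0.50, HOXA5 fell by 1.11 and the satellite cell gene CDH15 was higher by 0.73 ± 0.17.

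**Figure D4:**
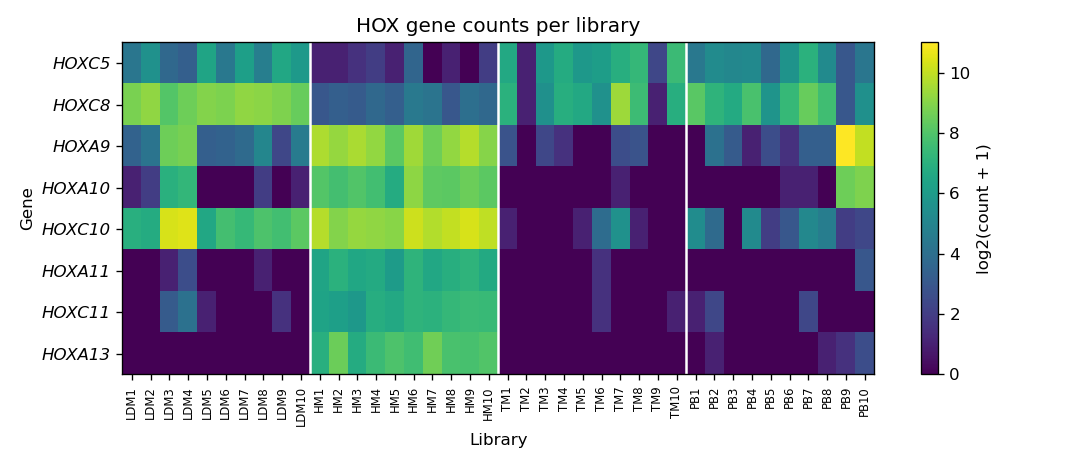
Counts of 8 HOX genes in each of the 40 libraries, as log2 of the count plus 1, with libraries ordered by cut and number. HOXA13 lies between 108 and 393 counts in the 10 HM libraries and at 0 in LDM and TM, and HOXA10 is on in LDM3, LDM4, PB9 and PB10.

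In edgeR 0 of 13 slow fibre and 0 of 16 glycolysis genes passed between TM and HM, with 1 each at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom. Nor did MYH7 at 0.50 ± 0.32, MYH4-MYH1-MYH2 at -0.29 ± 0.23, ADIPOQ at 0.84 ± 0.57, FASN at -0.02 ± 0.28, SCD at 0.06 ± 0.38, PPARGC1A at -0.02 ± 0.65, MSTN at -1.47 ± 0.42, COL1A1 at -0.03 ± 0.39 and PTPRC at -0.49 ± 0.45 pass. Of the 90 genes 48 were higher and 42 lower in TM, and 51 passed by 2-fold or more, 19 higher and 32 lower. On the pair alone 29 were higher and 45 lower, while 213 passed with the number as a block (104 higher and 109 lower), 199 with DESeq2 (92 and 107) and 312 with limma-voom (140 and 172). By 2-fold or more, 89 passed with DESeq2 and 101 with limma-voom, and 35 were higher and 35 lower without HM6, HM9, TM3 and TM7 and 31 each without number 8. Without TM2 or TM4 the count was 52, with 33 by 2-fold or more, and without HM6 it was 135, with 66. CDH15 lost its call without HM5, HM7, TM1, TM2 or TM4 (adjusted p up to 0.0895) and HOXA5 without HM3, HM7, HM8, HM10, LDM5, LDM9, TM2, TM3, TM4, TM5, TM9 or TM10 (up to 0.0855). CDH15 also lost it on the pair alone, and HOXA5 with upper-quartile scaling and without HM6, HM9, TM3 and TM7 (adjusted p = 0.0673, 0.0522 and 0.11, within ranges of 0.00689 to 0.0673 and 0.00601 to 0.11). With limma-voom HOXA9 stood at -8.74 and IRX3 at 5.66, and with the number as a block HOXA9 at -9.26. Without LDM2 MSTN passed (adjusted p = 0.0454), as it did with DESeq2 and on the pair alone (adjusted p = 0.0322 and 0.0228, within a range of 0.0228 to 0.119). TM6 held the 2 HOXA11 counts of TM and 2 of its 3 HOXC11 counts, and without HM6 HOXC5 stood at 5.68.

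Of the 9 lists called, HOX groups 10 to 13 alone passed with an estimated correlation. Beside the HOX lists, adipocyte (2.74e-05), fatty acid oxidation (0.00153) and ribosomal protein genes (0.0224) were higher in TM than in HM, with adjusted p = 0.298, 0.688 and 0.84 with an estimated correlation. Mitochondrially encoded (1.89e-10), immediate early (3.97e-06), heat shock (0.0161) and fast fibre genes (0.0183) were lower, with adjusted p = 0.199, 0.614, 0.823 and 0.823 with an estimated correlation. Over all genes tested, 0 members of the mitochondrial list passed in edgeR, with 11 of 12 at an unadjusted p under 0.05, 2 in DESeq2 and 7 in limma-voom. The adipocyte, fatty acid, immediate early, heat shock, ribosomal protein and fast fibre lists also had 0 in edgeR, with 6, 4, 8, 6, 2 and 5 members at an unadjusted p under 0.05, 1, 1, 3, 1, 0 and 0 in DESeq2 and 0, 1, 0, 1, 0 and 0 in limma-voom. Adjusted over the list alone, 7 HOX genes of groups 1 to 5, 2 adipocyte genes and 1 fatty acid gene were higher, and 5 HOX genes of groups 10 to 13, 1 of groups 1 to 5, 11 mitochondrial, 7 immediate early and 3 heat shock genes were lower. The fast fibre genes did not pass without number 8 (adjusted p = 0.127) or without HM6, HM9, TM3 and TM7 (adjusted p = 0.0652). With fry the fast fibre, fatty acid, immediate early, heat shock and ribosomal protein genes did not pass (adjusted p = 0.364, 0.223, 0.123, 0.364 and 0.575).

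In no pair did 7 lists pass by camera: the lowest adjusted p over the 6 pairs was 0.115 for myeloid genes, 0.0776 for Schwann cell genes, 0.222 for skin epithelium genes, 0.405 for neuromuscular junction genes, 0.285 for satellite cell genes, 0.0537 for other positional factors and 0.115 for calpains, cathepsins and ubiquitin ligases. The lymphocyte list had 2 tested genes and the red blood cell list 1, ALAS2, and in edgeR 0 of them passed in any pair, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom. In 51 called results of a list in a pair, the median, the mean and the test had the same sign in each, and in 21 results that were not called they differed.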

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

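The tests of the explanations weighed for 3 patterns, and the bounds by which the splits of the libraries were read, were chosen only after the results were seen.

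All 12 tested mitochondrially encoded genes rose in PB over LDM, by a median log2 of 2.20. COX1 rose less, from 2.24% of counts to 3.35%, below its 3.72% in HM. A trend with gene length as the whole cause is argued against by the median of 2.419 with the number as a block and a length correction. A scaling set by a few abundant genes is argued against by the lowest median under RLE and upper-quartile scaling, 2.21, and a joint rise of all oxidative phosphorylation transcripts by the nuclear-encoded median of 0.134. A difference in mitochondrial content or in RNA recovery between the cuts may remain and was not tested.

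By correlation with the cut means over all genes tested, HM6, HM9, TM3 and TM7 lay nearest to another cut, but TM3 to its own over the 1000 most variable genes. A wrong label on HM6 and HM9 is argued against by HOXA13, near 0 outside HM, whose lower count in these libraries was 194, against 108 to 393 over HM. For TM3 as HM tissue, HOXA13 stood at 0. For TM7 as LDM tissue, 2 of 8 positional genes lay in the range of the LDM libraries and 4 in that of the other TM libraries, so a wrong label and a place in the trapezius near the back cannot be told apart for TM7, as the genes go both ways. With the 4 libraries left out, COL1A1 in TM against HM stood at 0.31 and MYH7 in PB against HM at -0.07, and other causes of the places of HM6, HM9 and TM3 were not tested.

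HOXA10 was on in LDM3, LDM4, PB9 and PB10, at 127, 156, 380 and 471 counts, and at 3 or fewer in the rest of LDM and PB. RNA carried over from HM tissue is argued against, because HOXA13 had 7 counts over these 4 libraries where the HM ratio of 0.803 and 1134 HOXA10 counts predict 911. A trait of these animals in every cut is argued against by PB3, PB4, LDM9 and LDM10, where the highest HOXA10 count was 1. A sampling site farther back along the body in these 4 libraries is a candidate explanation, which the labels do not record and which was not tested.

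Of 456 groups of 10 values tested for a library far from the others of its cut, 46 held one (10.1%), where chance gives about 23. The values below are its gap to the nearest other library divided by the range of the cut, on the linear scale for genes detected and total counts and on log2 CPM with a prior count of 2 for single genes, while the levels of ACTA2 are plain CPM. HM6 had 14768 genes detected against 13668 to 14039 in the rest of HM (0.663), and TM10 the highest total count of TM (0.516). HM6 was also far above the other HM libraries in SIM1 (0.68), HOXC5 (0.508), CFD (0.568), COL15A1 (0.511), SHOX2 (0.475), MYLK (0.668) and ACTA2 (0.567), with 3168 CPM against 147 to 556. PB8 was far above the rest of PB in PTPRC (0.584) and far below it in NDUFS1 (0.638), DLD (0.589), GPAM (0.598), RGS5 (0.603), COX5B (0.507), CD36 (0.514), ETFA (0.627), LPIN1 (0.539), MYLK (0.477), ACTA2 (0.479), NOTCH3 (0.769) and HOXB3 (0.621). HM5 was far above in EGR1 (0.505) and far below in HOXA11 (0.516) and CAPN3 (0.502), HM7 was far below in IRX3 (0.48) and HM9 in COX5B (0.489).

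In LDM, LDM2 was far above the others in SERPINB2 (0.574) and far below in GYS1 (0.516), and LDM10 far below in NPR3 (0.626), ERG (0.519) and CAST (0.49). LDM4 was far above in CLCA4 (0.487) and HOXA11 (0.63) and far below in NRSN1 (0.665) and COL15A1 (0.467), and LDM7 far below in DUSP1 (0.52) and EGR1 (0.467). TM7 was far below the other TM libraries in RFLNA (0.481), ATP2A2 (0.482) and IDH2 (0.468), and TM9 far above in THBS4 (0.586). Counts near 0 set some of these: PB10 alone of PB had HOXA11 counts (7), TM6 alone of TM had HOXA11 counts (2) and TM7 alone of TM had HOXA10 counts (1), which gives a value of 1 each, and TM6 stood at 0.516 in HOXC11.

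The libraries of each pair were split 100 ways, the real split included. In each pair only the real split, 1 of 100 and the fewest possible, gave so many genes. The same held for genes with 2-fold or more and for those differing among the 4 cuts, which argues against chance. The highest other count was 2627 against 4880 in PB-LDM, 2036 against 3232 in PB-HM, 1943 against 2706 in PB-TM, 427 against 2898 in TM-LDM, 1576 against 3805 in HM-LDM and 2 against 90 in TM-HM, and with 2-fold or more 644, 501, 534, 149, 385 and 2 against 1417, 908, 748, 720, 956 and 51. For genes differing among the 4 cuts it was 359 against 6695. Among the splits that part as many pairs of equal number as the real one, the highest was the same, except for 1 in TM-HM on both counts.

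For the number of gene lists called, chance cannot be excluded in any pair. As many as the real split came in 73 of 100 splits in PB-LDM, 97 in PB-HM, 76 in PB-TM, 12 in TM-LDM, 21 in HM-LDM and 60 in TM-HM. The real numbers were 7, 5, 7, 11, 12 and 9, and the highest other numbers 15, 15, 13, 13, 15 and 15, or 14, 15, 12, 13, 15 and 14 among the splits that part as many pairs. Other splits of the same libraries calling more lists than the real one points to genes that move together across libraries whatever the cut.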

How the results depend on the processing

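The 4 added alternatives were chosen only after the results were seen, and the others were planned. In the pairs other than TM-HM, the counts of genes called, also with 2-fold or more, stayed within 1.5 times under every alternative named here and with any 1 library left out, and 6274 to 7502 genes differed among the 4 cuts. In TM-HM 90 genes became 199 with DESeq2 and 312 with limma-voom, and 51 with 2-fold or more became 89 and 101. Leaving out 1 library gave 52 to 135 genes, and 33 to 66 with 2-fold or more. The number of lists called fell to 1 with an estimated correlation in each of the pairs PB-LDM, PB-HM, PB-TM, HM-LDM and TM-HM and to 0 in TM-LDM, and with fry to 2 in PB-TM and 4 in TM-HM. A test with an estimated correlation asks more of a list whose genes move together, and elsewhere the cause was not tested. Depth limits the genes at a few counts, such as HOXA10, HOXA11 and HOXC11 in TM, and LEP, which had too few counts to be tested. No alternative scaling moved the median of all genes by over 0.1 on the log2 scale.

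Of 314 results of a named gene in a pair, those that lost their call numbered 6 under RLE scaling, 2 under upper-quartile scaling, 14 with no filter, 10 without PB1, 7 without the 4 libraries, 23 of 313 without number 8, 8 of 304 without mitochondrially encoded genes, 12 of 291 in the pair alone, 2 with DESeq2, 24 with limma-voom and 37 when 1 library was left out. A call was gained by 1 result without number 8, 2 in the pair alone, 1 with DESeq2 and 4 when 1 library was left out. The filter of 1 CPM in 10 libraries kept each of the 310 results it tested. Results missing here belong to genes that the filter or the setting took out. Of 51 calls of a list, 46 were lost with an estimated correlation, 16 with fry, 6 without PB1, 1 without the 4 libraries, 4 without number 8 and 0 with RLE.

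The direction turned in 14 results, none of which passed in edgeR with all libraries, and the cause was not tested. The log2 values were, without number 8, 0.031 for MYH4-MYH1-MYH2 and -0.014 for SCD in PB-LDM, -0.01 for PTPRC in PB-HM, -0.217 for PTPRC in TM-LDM, and -0.008 for SCD and 0.366 for PPARGC1A in TM-HM. Without PB1 they were -0.011 for ADIPOQ in PB-LDM and -0.37 and -0.344 for COL1A1 in PB-HM and PB-TM. Without the 4 libraries they were -0.073 for MYH7 in PB-HM, and 0.149 for PPARGC1A and 0.31 for COL1A1 in TM-HM. Without mitochondrially encoded genes they were 0.009 for PPARGC1A in PB-LDM and 0.003 for both FASN and COL1A1 in TM-HM. In TM-HM, upper-quartile scaling gave 0.018 for FASN, 0.008 for PPARGC1A and 0.001 for COL1A1, and the pair alone 0.006, 0.006 and 0.003. With limma-voom they were -0.124 for ADIPOQ in PB-LDM, -0.085 for COL1A1 in PB-TM, 0.015 for FASN in HM-LDM and 0.108 for COL1A1 in TM-HM.

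With 1 library left out the log2 value ran, in PB-LDM, from -0.216 to 0.039 for MYH4-MYH1-MYH2, -0.135 to 0.287 for ADIPOQ, -0.234 to 0.151 for SCD and -0.965 to 0.171 for PPARGC1A. It ran in PB-HM from -0.37 to 0.446 for COL1A1 and -0.032 to 1.02 for PTPRC, in PB-TM from -0.344 to 0.264 for COL1A1, in TM-LDM from -0.099 to 0.314 for PTPRC and in HM-LDM from -0.235 to 0.03 for FASN. In TM-HM it ran from -0.146 to 0.169 for FASN, -0.095 to 0.295 for SCD, -0.646 to 0.195 for PPARGC1A and -0.121 to 0.279 for COL1A1. Leaving out PB1, which turned 3 of these, left MYH4-MYH1-MYH2 at -0.109, SCD at 0.032 and PPARGC1A at -0.084 in PB-LDM, PTPRC at 0.979 in PB-HM and 0.073 in TM-LDM, FASN at -0.062 in HM-LDM, and FASN at -0.02, SCD at 0.063 and PPARGC1A at -0.022 in TM-HM.

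With the number as a block, the pairing raised the genes called in TM-HM to 213, and to 209 with the length correction, and of the named genes 6 results lost their call, or 13, with 1 gained, with the length correction. The block turned ADIPOQ in PB-LDM to -0.051 (-0.05 with the length correction), COL1A1 in PB-HM to -0.031 (-0.01), in PB-TM to -0.067 (-0.08) and in TM-HM to 0.036 (0.069), and PTPRC in TM-LDM to -0.026 (-0.074), and the length correction also FASN in TM-HM to 0.029. Beyond these and the results given with the block beside them, the block alone changed no other call, and the cause was not tested.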

Other observations

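The values below, and the genes and libraries they belong to, were chosen only after the results were seen, and no further tests were run on them.

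Of the 6695 genes that differed among the 4 cuts, LDM had the highest mean in 2319 (34.6%), PB in 2027 (30.3%), HM in 1498 (22.4%) and TM in 851 (12.7%). The lowest mean lay in LDM for 2319, in PB for 2113, in HM for 1335 and in TM for 928.

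HOX genes varied within cuts as well as between them. HOXC10 stood at 1288 counts in LDM3, 1406 in LDM4 and 96 to 296 in the rest of LDM, and HOXA9 at 384 and 431 against 4 to 32. In PB9 and PB10, where HOXA9 was high, HOXC8 had 7 and 45 counts. In TM, HOXC8 had 1 count each in TM2 and TM9 and 677 in TM7, against 45 to 185 in the rest, and HOXC5 1 and 4 in TM2 and TM9.

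The labels call the pigs male. Summed over its 4 libraries, number 8 had 0 counts of the Y-linked gene ZFY, 1 of EIF1AY and 0 of KDM5D, where the other numbers had 697 to 1201, 748 to 1266 and 55 to 147. Over the 11 genes of chromosome Y with the most counts, number 8 had 6840 counts and the other numbers 13430 to 18622. The gene ENSSSCG00000044574 on chromosome 7 had 456 to 1760 counts in each library of 5 numbers and 2 to 21 in each library of the others.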
